A study of Mus musculus with 32 samples.

How the data were processed

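Total RNA was sequenced from dissected parts of the digestive tract of wild-type mice and of mice homozygous for a deletion, called percc1-/- in the labels. Per the labels' protocols, RNA was taken with TRIzol from frozen tissue emptied of its contents, and libraries were stranded, with ribosomal RNA removed by the Ribo-Zero method. The targeted allele was made in W4/129S6 embryonic stem cells, and the line was kept on a mixed 129Sv and C57 background by sibling breeding, per the labels' protocols.

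The 32 libraries formed 16 pairs, each of 1 percc1-/- and 1 wild-type library of the same region and stage. Small intestine gave 7 pairs, from the top part (P1, P5, P15) and the bottom part (P1, P5, P10, P20). Stomach gave 5 pairs, from the whole organ (P1, P5) and its bottom part (P10, P15, P20). Large bowel gave 3 pairs (colon with rectum at P1, colon at P5, rectum at P5), and the whole gut at E14.5 gave 1. The pairing came from the region and stage in the labels. The labels do not say whether the libraries come from separate animals, or whether regions of one stage come from the same animals, so that p-values measure the spread between pairs, which may be partly technical, and may be too small.

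The authors deposited 1 Cufflinks gene table per library, with an FPKM and its lower and upper bounds for each record. FPKM is a fragment number scaled to transcript length and to the mapped fragments of the library. TopHat2 2.0.13, SAMtools 0.1.18, Cufflinks 2.2.1 and the mm9 genome are named in the submitters' processing notes. The annotation version is not given in the sources used here. Each table held records with a gene symbol and records without one. Only records with a symbol entered the tests, and records of one symbol were summed within a library. Records with a failed status left their genes missing in that library, and a gene missing in any library of a fit was left out of that fit. Genes held in a record that merged several symbols were treated in the same way, a step decided after the tables had been read.

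The files hold no counts. The number of fragments per library, estimated from the width of the deposited FPKM bounds, lay between 4580000 and 12400000, which is an approximation and gives no counting interval. A value of 0 was not read as absence of a transcript, since abundant genes were among those with one. Of 4643 genes with a mean of at least 10 FPKM, 51 were listed at 0 in some library, with a median of 5 such genes per library. Genes at 0 are therefore described as listed at 0, with the range over libraries.

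Libraries were rescaled by the median ratio to the geometric-mean library over genes above 1 FPKM in every library. Tests were run in R 4.3.3 with limma 3.58.1 on log2(rescaled FPKM + 1), with a trended and robust variance prior, for genes with a mean of at least 1 FPKM over the libraries of the fit. A fold change on this scale understates the change of genes at low levels, and a fall cannot exceed the level in the other group. Adjusted p-values follow Benjamini and Hochberg, and genes under 0.05 were called. Genotype was fitted with the pair as a block over all pairs and within each region. Further fits tested whether the genotype effect differed between stomach and small intestine and between younger (P1, P5) and older (P10 to P20) small intestine. The stage comparison in small intestine had the part of the intestine and the genotype as covariates, and stomach against small intestine had stage and genotype. The single whole gut pair was described without a test. All p-values are two-sided.

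Gene lists for gut cell types, hormones, endocrine granules, nutrition, immunity and neighbouring organs were fixed before the data were examined, as were the tests above and most of the alternative settings below. The 27 lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, and again with a correlation estimated from the data. The mean log2 ratio of the hormone list per pair was tested by an exact sign-flip permutation test.

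Genes are named by a rule fixed before the data were examined. It takes every expressed hormone of the list, up to 10 largest rises and 10 largest falls among called genes with the same sign in at least 80 percent of pairs, the 5 smallest p-values where fewer than 5 genes passed, and up to 4 called members of each list. For stage and region comparisons and for differences between effects it takes up to 5 each way. For the whole gut pair it takes the hormones above 1 FPKM in either library and the 5 largest rises and falls among genes of at least 5 FPKM in either library. Not every gene that meets the rule is printed. Genes named outside it are said to have been chosen after their values were seen.

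The gene test was tested on simulated data with 200 changed genes in each comparison. Simulated libraries shared no spread within a stage, so the recovery and false calls below hold for independent pairs only. Over all pairs, 80.6, 98.5 and 100 percent of genes changed by 0.5, 1 and 2 on the log2 scale were recovered among 13084 genes, and 5 unchanged genes were called. For a change of 1, 83.6 percent were recovered in small intestine, 67.2 percent in stomach, 1.49 percent in large bowel, 65.7 percent for the difference between regions and 25.4 percent for the difference between stages of the small intestine. A single planted change was called in the wrong direction. It was a planted difference of -2 for Gip between regions, which required values below 0 FPKM, and the fit returned 3.15 because such values were set to 0. In the list test, the 1 shifted list of 20 genes was called and 0 of 50 unshifted lists were. Simulated genes varied independently of each other, so this does not bear on lists whose genes vary together.

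Alternatives covered the pseudocount, the filter on low values, scaling, library weights, sex chromosomes, failed records, the pairing, averaging within stages, parts of an organ, and leaving out each pair. Pairs with markers of another organ (gastric, pancreas, liver or enterocyte lists), those with the whole gut and bottom stomach at P15, chromosome 17, merged records and unnamed records over Ghrl were added after the data were seen.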

Results

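The data described total RNA, with ribosomal RNA removed, in the digestive tract of wild-type and percc1-/- mice from E14.5 to P20. There were 16 libraries of each genotype, in 16 pairs of the same region and stage: 7 of small intestine, 5 of stomach, 3 of large bowel and 1 of whole gut. The tables gave FPKM and no counts, so the depth behind a value is known only through its FPKM bounds. Records with a gene symbol held between 16.8 percent of the FPKM sum, in the wild-type whole gut, and 60.2 percent, in the percc1-/- library of bottom stomach at P15.

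The targeted locus was examined first, as a check of the genotype labels. The labels state that 1512 bp of chromosome 17, from 25175032 to 25176543 on mm9, were replaced by a loxP site. In the reference annotation of mm9 these positions lie in the intron between exons 12 and 13 of a transcript of Ift140, a gene of transport within cilia, and overlap 0 of its exons. Ift140 did not pass (log2 change -0.03 ± 0.10 SE, adjusted p = 0.927, 16 pairs). Unnamed records lying wholly inside the stated positions were found in 4 of 16 percc1-/- and 0 of 16 wild-type libraries (Fisher's exact p = 0.101), and a wild-type record in bottom intestine at P10 reached into them. No record used here carried the symbol Percc1. In the RefSeq gene order of GRCm38, Percc1 lies between Ccdc154 and BC003965, and the same position numbers read on GRCm38 fall inside Percc1, so that the build of the stated positions is in doubt. Between the end of Clcn7 and the start of BC003965 (mm9 chromosome 17, 25299050 to 25321505), a window chosen after its values were seen, unnamed records were present in 5 of 5 wild-type stomach libraries, with summed FPKM of 5.16 to 13.9, and in 0 of 5 percc1-/- ones (Fisher's exact p = 0.00794). Over all regions they were present in 6 of 16 wild-type and 0 of 16 percc1-/- libraries (Fisher's exact p = 0.0177). The wild-type record outside stomach, in colon at P5 (1.22 FPKM), lay at 25320696 to 25321164, apart from those of stomach. As the window was chosen from these values, its p-values are not an independent check of the labels, and the records bear on stomach alone. Ccdc154, whose record lies in the window, had 0.203 to 0.601 FPKM in percc1-/- stomach against 0.761 to 1.83 in wild type. In small intestine it had 0 to 0.248 against 0.132 to 0.2.

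**Figure D1:**
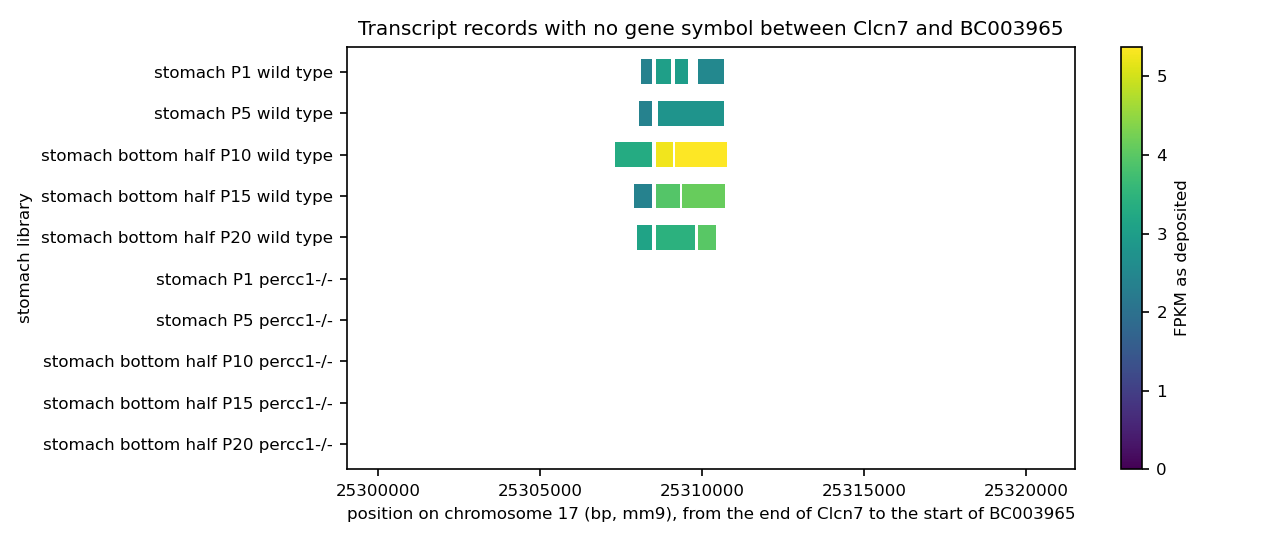
Unnamed records between Clcn7 and BC003965 in the 10 stomach libraries, drawn at their mm9 positions on chromosome 17 and coloured by FPKM. The 5 wild-type libraries hold records in the window and the 5 percc1-/- libraries hold 0.

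Across all 16 pairs, the question was what differs in the gut of percc1-/- mice, and peptide hormones of the enteroendocrine cells were among the largest falls. Ghrelin (Ghrl), the hunger hormone of the stomach, fell by 3.35 ± 0.37 on the log2 scale (SE, adjusted p = 6.79e-05, lower in 15 of 16 pairs). With unnamed records over the gene added, its mean log2 ratio was -1.37 (permutation p = 0.000854), against -3.35 without them. These records did not follow Ghrl in every library. They had 6.63 FPKM in wild-type colon at P5, where Ghrl was listed at 0. They had 0 in wild-type bottom stomach at P20, where Ghrl had 67.9. Their strand was not examined, so the sums here and below may hold other transcripts. Proglucagon (Gcg), the precursor of the GLP peptides, fell by 2.61 ± 0.24 (adjusted p = 6.91e-06, 16 of 16 pairs), and somatostatin (Sst), an inhibitor of other endocrine cells, fell by 1.87 ± 0.20 (adjusted p = 3.01e-05, 16 of 16). Pyy, Gip, Nts and Cck fell by 2.22, 2.21, 1.89 and 1.30 (adjusted p = 0.00421, 0.0232, 0.0318 and 0.0428, lower in 14, 15, 13 and 15 pairs). Of the 12 tested hormones, 7 fell, 1 rose (Tac1, the substance P precursor, log2 0.40 ± 0.09, adjusted p = 0.0297, 14 pairs higher) and 4 did not pass. Those were Insl5 (-0.84, adjusted p = 0.241), Gast (-0.66, 0.173), Iapp (-0.43, 0.253) and Sct (-0.41, 0.295). Adjusted over the list alone, 11 fell and 1 rose. As a list the hormones fell against all other genes (camera adjusted p = 2.67e-14; adjusted p = 0.000383 with an estimated correlation). The mean log2 ratio of the list was -1.85 ± 0.52 (SD, n = 16 pairs), lower in 16 of 16 (exact sign-flip p = 3.05e-05, the smallest 16 pairs can give). Leaving out a single pair ended the call of Cck for 13 of the 16 pairs, of Nts for 7, of Tac1 for 6 and of Gip for 4 (bottom intestine at P1, P5 and P10, top intestine at P1). Without 7 pairs in which markers of stomach, pancreas, liver or enterocytes differed, Pyy, Gip, Nts, Sst, Cck and Tac1 had changes of -2.45, -2.34, -1.78, -1.67, -1.21 and 0.41 and did not pass with fewer pairs (adjusted p = 0.125, 0.339, 0.424, 0.068, 0.42 and 0.219). The list kept its call there (camera adjusted p = 1.90e-10).

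**Figure D2:**
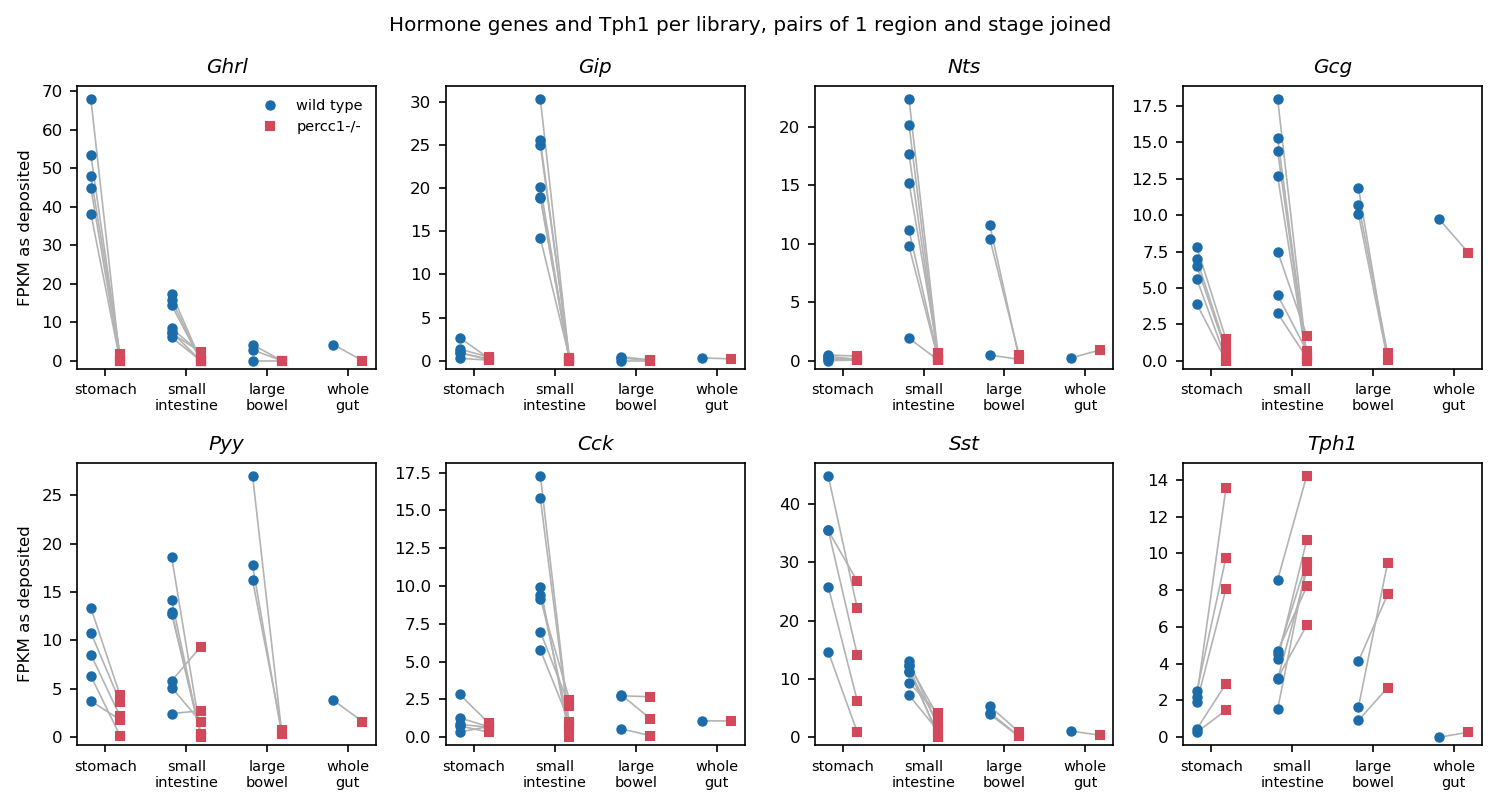
FPKM as deposited of Ghrl, Gip, Nts, Gcg, Pyy, Cck, Sst and Tph1 in each library, by region, with wild type as circles, percc1-/- as squares and the 2 libraries of a pair joined. Gcg and Sst are lower and Tph1 is higher in percc1-/- in 16 of 16 pairs.

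Of 19 tested granule and amine genes of enteroendocrine cells, 3 rose and 0 fell. Tph1, which makes serotonin in enterochromaffin cells, rose by 1.22 ± 0.12 log2 (SE, adjusted p = 2.40e-05, higher in 16 of 16 pairs). The granule proteins Chgb (log2 0.49 ± 0.07, 18.4 ± 7.45 against 12.9 ± 4.67 FPKM, SD, n = 16, adjusted p = 0.00203, 16 of 16) and Chga (0.41 ± 0.09, adjusted p = 0.0282, 14 of 16) rose as well. Adjusted over the list alone 4 rose, and the list did not pass (camera adjusted p = 0.277). Enteric neurons, which also express Chga, Chgb and Tac1, had 19 of 19 tested list genes positive (median log2 0.16). The call of Chga ended on leaving out any 1 of 8 pairs, and without the 7 pairs with such markers Chgb (0.50, adjusted p = 0.142) and Chga (0.42, 0.381) did not pass, with changes of about the same size. Of 13 endocrine transcription factors, 0 passed in limma, against 1 rise and 1 fall adjusted over the list alone (camera adjusted p = 0.265).

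Among the largest rises over the 16 pairs were Saa3, an acute phase protein (2.13 ± 0.28 log2, SE, adjusted p = 0.000491, 16 of 16 pairs), the neutrophil calprotectin subunits S100a8 (1.67 ± 0.27, 0.0044, 14) and S100a9 (1.36 ± 0.29, 0.0308, 14), and Lcn2, an iron-binding antibacterial protein (1.53 ± 0.29, 0.0148, 15). The antibacterial lectins Reg3g (1.5 ± 0.30, 0.0198, 15) and Reg3b (1.32 ± 0.27, 0.0232, 14) rose, as did Hp, Stfa2 and Gm5483 (1.52, 1.27 and 1.29, adjusted p = 0.0391, 0.0148 and 0.0319). Trim12a (-1.35 ± 0.24, adjusted p = 0.00891) and Trim30d (-1.34 ± 0.31, 0.0438) fell, each in 14 of 16 pairs. Of 17 tested antimicrobial and interferon genes, 4 rose and 1 fell, 5 rose and 5 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.232). The call of Trim30d ended on leaving out any 1 of 13 pairs, of Hp and S100a9 any 1 of 8, of Gm5483 any 1 of 7, and of Reg3b bottom intestine at P10 or top intestine at P1. Without the 7 pairs with markers of another organ each of these genes lost its call, with Saa3 at 1.78 (adjusted p = 0.0952), S100a8 at 1.19 (0.381), Lcn2 at 1.06 (0.33), Reg3g at 1.45 (0.339) and Trim12a at -0.92 (0.392).

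Genes of the fasting and stress response list, called fasting genes below, rose as a list (17 tested, camera adjusted p = 9.37e-08, adjusted p = 0.0011 with an estimated correlation). Of these 2 rose, Fkbp5, a glucocorticoid-induced chaperone on chromosome 17 (1.15 ± 0.18 log2, 12.8 ± 7.23 against 4.84 ± 1.93 FPKM, adjusted p = 0.00308, 14 of 16 pairs), and Pdk4, which spares glucose in fasting (0.87 ± 0.17, 12.5 ± 7.05 against 6.65 ± 4.23, 0.017, 15), and 10 rose adjusted over the list alone. Without the 7 pairs with markers of another organ, Fkbp5, Pdk4 and Gal had changes of 0.97, 0.92 and 0.50 and did not pass with fewer pairs (adjusted p = 0.381, 0.381 and 0.307). The list tests took the pairs as independent, and of the lists only the hormones were averaged within stages. Regions of a stage may share animals, so the p-values of the fasting genes and of the other lists may be too small. The enteric neuron list rose (19 tested, 19 positive; Gal 0.47 ± 0.11, adjusted p = 0.0406, a call that ended on leaving out any 1 of 12 pairs; 6 rises adjusted over the list alone; camera adjusted p = 1.27e-06; adjusted p = 0.28 with an estimated correlation). The immediate early genes rose (11 of 11 positive, 0 called, 8 adjusted over the list alone; camera adjusted p = 1.22e-07; adjusted p = 0.101 with an estimated correlation). Lists that fell were proliferation (19 of 20 negative, 0 called, adjusted p = 0.00189), leukocyte (10 of 12 negative, 0 called, 4 falls adjusted over the list alone, adjusted p = 0.00514) and exocrine pancreas (20 of 22 negative, 0 called, adjusted p = 0.00165). With an estimated correlation, adjusted p = 0.691 for proliferation and pancreas and 0.63 for leukocyte. Pancreas markers differed by -2.33 and -2.68 in top intestine at P1 and P5, -2.23 and -1.71 in stomach at P1 and P5, and 1.67 in bottom stomach at P10. Without the 7 pairs with markers of another organ the pancreas median was 0.056 (adjusted p = 0.611) and proliferation did not pass (0.0567), and without top intestine at P5 alone pancreas lost its call. The goblet list rose (12 tested, 0 called, adjusted p = 0.043), a call that ended without any 1 of 6 pairs (the 3 of large bowel, bottom intestine at P10, top intestine at P1, bottom stomach at P10) and without the 7 pairs (median 0.0318, adjusted p = 0.448). Its adjusted p with an estimated correlation was 0.63. The other 19 of the 27 lists did not pass, with adjusted p between 0.0783 (weaned enterocyte) and 0.971 (enterocyte absorption, suckling enterocyte, crypt stem, interstitial cells). Without the 7 pairs enterocyte absorption (median -0.171, camera adjusted p = 0.00406) and liver (-0.182, 0.0153) passed. Without the whole gut and bottom stomach at P15 as well, weaned enterocyte (0.335, 0.0272) and smooth muscle (-0.0912, 0.00926) passed. These 4 calls were not tried with an estimated correlation.

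In all, 116 of 13084 tested genes passed, 51 higher and 65 lower, and 1727 had an unadjusted p under 0.05 against 654 from chance. Of the 116, 29 lie on chromosome 17, which carries the targeted locus, or 4.64 percent of its 625 tested genes against 0.698 percent elsewhere (Fisher's exact p = 9.45e-14). Chromosome 6, which carries Ghrl, came next with 14 of 664 (2.11 percent). Of these 29, 14 were higher and 15 lower, 25 lay over 500 kb from the stated positions, and they include Gm3448 (1.81 ± 0.21, adjusted p = 0.000155), 3300005D01Rik (-1.11 ± 0.24, 0.0364, a call that ended on leaving out any 1 of 8 pairs) and Fkbp5. Markers of stomach, pancreas, liver or enterocytes, each where the organ was another, differed by over 1 log2 unit in 7 of the 16 pairs. Without these pairs 9 genes passed, among them Ghrl (-3.10, adjusted p = 0.0337), Gcg (-2.80, 0.00955), Tph1 (1.15, 0.0385) and Gm3448 (1.81, 0.00373). Skeletal muscle markers differed by -2.62 in bottom stomach at P15, and lung and heart genes in the whole gut. Without these 2 pairs as well 3 genes passed, Gcg (-3.19, adjusted p = 0.00333), Gm3448 (2.01, 0.00333) and Glo1 of chromosome 17, while Ghrl (-2.93, 0.116) and Tph1 (1.17, 0.112) did not. With differences averaged within stages 2 genes passed, Ghrl (-3.31, adjusted p = 0.000715) and Glo1, while Gcg (-2.35) and Tph1 (1.13) did not (0.0694 each). Glo1 was chosen after its values were seen. The count was 44 without the pairs in the model, 68, 70, 75, 75 and 69 without colon at P5, colon with rectum at P1, bottom intestine at P10 or P5, or top intestine at P1, and 182 without the whole gut.

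**Figure D3:**
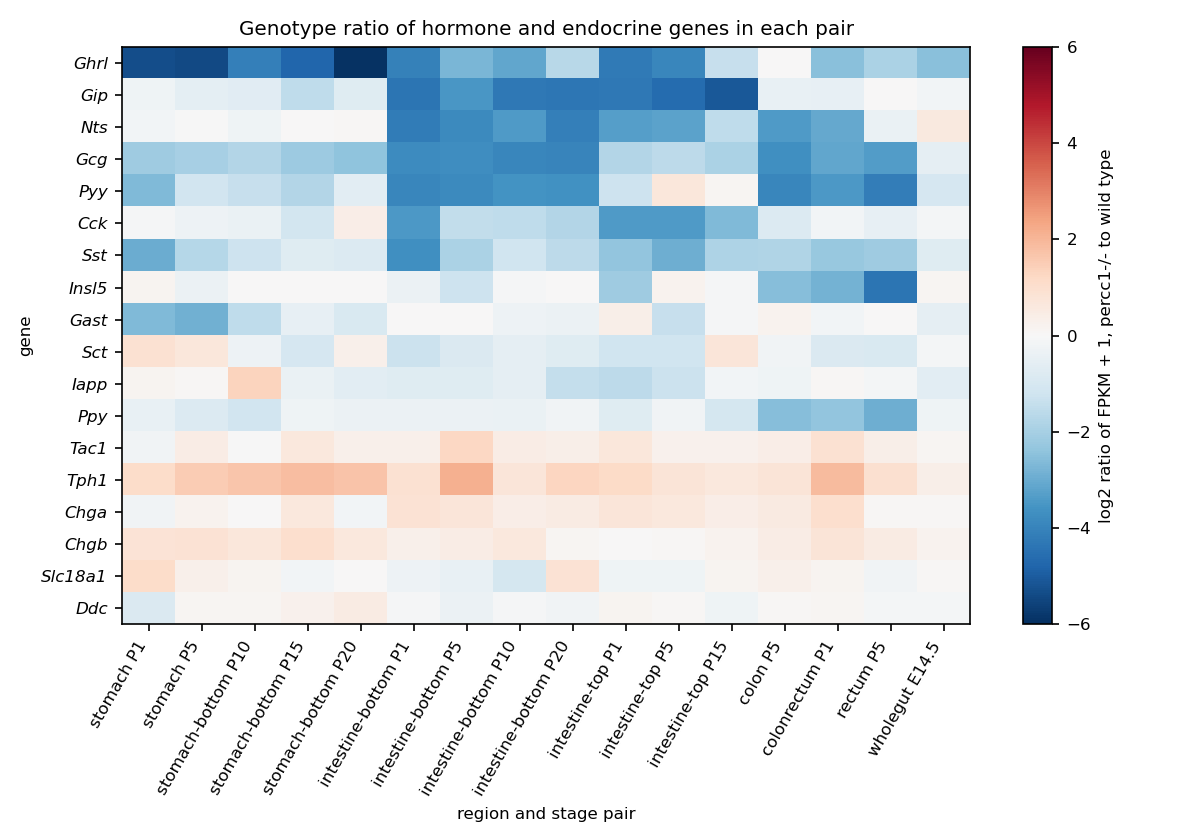
Log2 ratio of percc1-/- to wild type (FPKM + 1) for 18 genes in each of the 16 pairs, as a colour map. Gcg and Sst are lower and Tph1 and Chgb higher in 16 of 16 pairs.

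**Figure D4:**
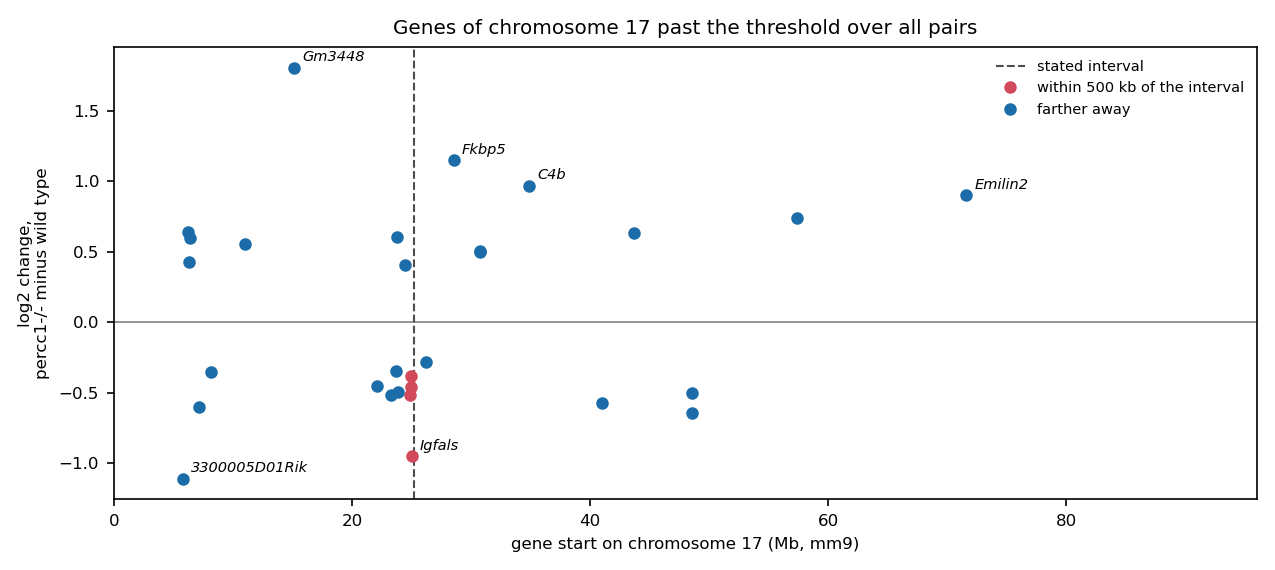
Log2 change over all pairs of the 29 called genes of chromosome 17 against their mm9 position, with those within 500 kb of the stated positions (dashed line) marked apart. Of the 29, 25 lie farther away, and 14 are higher and 15 lower.

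In small intestine, 6 hormones fell, in 7 of 7 pairs each. Gip, an incretin of the upper intestine, had 21.9 ± 5.38 FPKM in wild type (SD, n = 7) and 0 to 0.345 in percc1-/-, where 3 libraries listed it at 0 (log2 -4.32 ± 0.16 SE, adjusted p = 6.19e-06). Neurotensin (Nts) had 14.1 ± 7.02 FPKM in wild type and 0.0608 to 0.672 in percc1-/- (-3.35 ± 0.28, adjusted p = 0.00407). Ghrl, Gcg, Cck and Sst had wild-type means of 10.9, 10.8, 10.6 and 11 FPKM and reached at most 2.21, 1.70, 2.47 and 4.06 in percc1-/- (-3.0, -2.92, -2.50 and -2.20, adjusted p = 0.0239, 0.0239, 0.0239 and 0.0249). With unnamed records over Ghrl added, the sums were 3.24 to 13.6 FPKM in percc1-/- against 14.4 to 23.7 in wild type, so that the fall of Ghrl was smaller on this measure. Islet genes (2 tested, Iapp among them) differed by -2.24 and -1.91 in top intestine at P1 and P5. Pyy (-2.19, adjusted p = 0.265, 5 of 7 lower), Sct (-0.72, 0.316), Insl5 (-0.52, 0.56) and Tac1 (0.50, 0.227) did not pass. Of 10 tested hormones, 6 fell and 0 rose, against 8 and 1 adjusted over the list alone (camera adjusted p = 1.27e-15; adjusted p = 0.0163 with an estimated correlation), and the list mean was -2.12 ± 0.454 (SD, 7 of 7 lower, exact p = 0.0156, the smallest possible).

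Outside the hormones, the epithelial gene Gprc5a rose in small intestine from 0.775 ± 0.584 to 4.33 ± 1.83 FPKM (SD, n = 7; log2 1.56 ± 0.19, adjusted p = 0.0239). Saa3 (2.54 ± 0.35, adjusted p = 0.0398), the complement gene C3 of chromosome 17 (0.85 ± 0.12, 0.0465), Dhrs9 (0.79 ± 0.11, 0.0385) and Chga (0.61 ± 0.08, 0.0335) rose. The mast cell proteases Mcpt1 (0.507 ± 0.412 against 3.31 ± 1.91 FPKM, -1.42 ± 0.17, 0.0239) and Mcpt2 (-1.01 ± 0.13, 0.0385) fell, as did Tagap1 (-0.66 ± 0.09, 0.0409) and Hagh (-0.60 ± 0.09, 0.0473) of chromosome 17. The leukocyte list fell (15 of 15 negative, 0 called, 3 falls adjusted over the list alone; camera adjusted p = 2.25e-06; adjusted p = 0.0472 with an estimated correlation), and the fasting list rose (17 tested, 0 called, 3 rises adjusted over the list alone; 8.29e-05; adjusted p = 0.0472 with an estimated correlation). In all 15 of 12733 genes passed, 5 higher and 10 lower, with 1294 at an unadjusted p under 0.05. The count was 1 without the pairs with markers of another organ, where Gip alone of the named genes passed (-4.48, adjusted p = 0.00181) and those that did not had, among others, changes of -3.27 (Nts), -3.35 (Gcg), -2.54 (Ghrl), -2.32 (Cck), -2.06 (Sst), 1.59 (Gprc5a) and -1.42 (Mcpt1). It was 2, 5, 4, 2 and 5 without bottom intestine at P10, P1 or P5 or top intestine at P1 or P5. Each of the other named genes except Nts lost its call in at least 4 of the 7 omissions of 1 pair.

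In stomach, Ghrl had 50.5 ± 11.2 FPKM in wild type (SD, n = 5) and 0 to 1.71 in percc1-/-, where 3 of 5 libraries listed it at 0 (log2 -5.17 ± 0.26 SE, adjusted p = 0.00141). With unnamed records over Ghrl added, the sums were 5.54 to 10.6 FPKM in percc1-/- against 39.9 to 67.9 in wild type. Gcg fell from 6.16 ± 1.5 to between 0 and 1.49 FPKM (-2.13 ± 0.14, adjusted p = 0.00467), and Tph1 rose from 1.46 ± 1.03 to 7.15 ± 4.97 (1.59 ± 0.14, 0.0333), each in 5 of 5 pairs. These were the 3 of 13392 genes that passed, and 618 had an unadjusted p under 0.05 against 670 from chance. Chgb (0.81, adjusted p = 0.0766, 5 of 5 higher), Gm3448 (1.95, 0.104), Gast, the acid-stimulating hormone of the antrum (-1.71, 0.755, 5 of 5 lower), Pyy (-1.54, 0.543, 5 of 5), Sst (-1.51, 0.755, 5 of 5), Iapp (0.11, adjusted p = 1) and Tac1 (0.23, 0.985) did not pass. Of the 7 tested hormones 2 fell, 5 adjusted over the list alone (camera adjusted p = 1.11e-09; adjusted p = 0.122 with an estimated correlation), and the list mean was -1.68 ± 0.419 (SD, 5 of 5 lower, exact p = 0.0625, the smallest 5 pairs can give). Of 26 lists 12 passed and 0 held with an estimated correlation; among them were fasting, higher (4.59e-05; adjusted p = 0.122 with an estimated correlation), exocrine pancreas (23 of 23 negative, 0.0162; adjusted p = 0.676 with an estimated correlation) and liver (14 of 14 positive, 0.00197; adjusted p = 0.636 with an estimated correlation). Pancreas markers differed by -2.23 in the pair at P1, -1.71 at P5 and 1.67 in bottom stomach at P10, enterocyte markers by 1.12 at P1, liver markers by 3.51 at P5, islet genes by 2.34 in bottom stomach at P10 and skeletal muscle markers by -2.62 in bottom stomach at P15. Stomach's own gastric mucous genes (11.6 against 27.5 rescaled FPKM) and parietal and chief genes (13.3 against 27.1) were also lower in percc1-/- at P1. That pair had the hormone list mean of -2.31, with Gast at 0 against 5.12 FPKM and Sst at 0.888 against 14.7. Without bottom stomach at P15 the count was 1, Gcg and Tph1 losing their calls, and Tph1 lost its call without 3 other pairs too (bottom stomach at P10 and P20, stomach at P5). Without the pairs with markers of another organ 2 pairs remained and the count was 0, with changes of -5.5 for Ghrl, -2.45 for Gcg and 1.83 for Tph1.

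In large bowel, Pyy, a hormone of the lower gut, fell from 20.3 ± 5.84 to 0.554 ± 0.227 FPKM (SD, n = 3; log2 -3.79 ± 0.18 SE, adjusted p = 0.0259) and Gcg from 10.9 ± 0.92 to 0.216 ± 0.255 (-3.34 ± 0.17, 0.0259). Ppy was listed at 0 in 3 of 3 percc1-/- libraries against 3.71 to 6.74 FPKM in wild type (adjusted p = 0.0489). The goblet cell product Retnlb (11.8 ± 3.71 against 1.93 ± 1.25 FPKM, 2.14 ± 0.14), the antibacterial lectin Reg3g (23.3 ± 14.9 against 5.07 ± 4.63, 2.08 ± 0.15) and the Paneth cell protease Mmp7 (9.19 ± 4.22 against 1.41 ± 0.937, 2.01 ± 0.14) rose, each at adjusted p = 0.0489 and in 3 of 3 pairs. These 6 of 13301 genes passed, 3 higher and 3 lower, with 1320 at an unadjusted p under 0.05 against 665 from chance. Sst (-2.03, adjusted p = 0.0907), Insl5 (-3.20, 0.218), Nts (-2.26, 0.415), Sct (-0.65, 0.413), Cck (-0.47, 0.518), Tac1 (0.55, 0.418) and Ghrl, at 0 in the 3 percc1-/- libraries (0.473), did not pass. With unnamed records over Ghrl added, percc1-/- had 7.30 against 6.63 FPKM in colon at P5, 10.1 against 5.03 in rectum at P5 and 6.30 against 9.49 in colon with rectum at P1. Of 10 tested hormones 3 fell, against 8 falls and 1 rise adjusted over the list alone (camera adjusted p = 5.42e-11; adjusted p = 0.489 with an estimated correlation). Goblet genes rose (13 tested, 1 called, 2 adjusted over the list alone, 1.11e-05), and so did genes of the Paneth list (7 tested, 1 called, 3 adjusted over the list alone, 0.00063). The cells behind Mmp7 and the Paneth list were not identified in large bowel, so these rises do not show Paneth cells there. Fasting genes (17 tested, 0 called, 7 adjusted over the list alone, 1.30e-05) and antimicrobial genes (18 tested, 1 called, 6 adjusted over the list alone, 0.00188) rose as well. With an estimated correlation, adjusted p = 0.489 for each of these 4 lists too, and 0 of the 10 lists that passed held. The hormone list mean was -1.92 ± 0.0823 (SD, 3 of 3 lower, exact p = 0.25, the smallest 3 pairs can give). The count was 0 without colon at P5, where gastric mucous markers differed by 1.64 and the changes were -3.76 for Pyy and -3.20 for Gcg, 0 without colon with rectum at P1, and 28 without rectum at P5.

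The whole gut at E14.5 had 1 library per genotype, so no test was made. Ghrl was listed at 0 in percc1-/- and had 4.2 FPKM in wild type. Unnamed records over the gene had 9.55 and 5.24 FPKM, giving sums of 9.55 in percc1-/- and 9.44 in wild type. Pyy had 1.62 against 3.81 FPKM, Sst 0.336 against 1.06, Iapp 3.67 against 5.46 and Gcg 7.41 against 9.71, while Sct had 4.91 against 4.77, Cck 1.07 against 1.08 and Tac1 1.36 against 1.02. The median log2 ratio of 7 hormones was -0.49, beside mean ratios of -0.43 for exocrine pancreas and -0.50 for 2 islet genes. The largest rises were Sftpc of lung (28.8 against 0.0657), Nppa (22.2 against 0.254) and Mybpc3 (16.8 against 0.165) of heart, and Chchd1 and 2410003K15Rik, at 0 in wild type. Ccdc45, Surf1, Surf2, Mir296 and Dap3 were listed at 0 in percc1-/- against 10.7, 7.78, 7.23, 6.20 and 5.71 in wild type.

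The difference of the genotype effect between stomach and small intestine was tested directly. Gip (3.6 ± 0.26 log2, SE, adjusted p = 3.54e-05) and Nts (3.30 ± 0.37, 0.0032) passed, with the smaller fall in stomach, among 13069 genes of which 622 had an unadjusted p under 0.05. In wild-type stomach Gip had 1.14 ± 0.831 and Nts 0.224 ± 0.183 rescaled FPKM, so that their falls there could not exceed 1.02 and 0.28. Cck, Sct and Insl5 were also low there (1.14, 0.65 and 0.0856), which limits the result of the hormone list in the same way. The next genes, Cck (2.22, adjusted p = 0.473), Gprc5a (-1.40, 0.497) and Ift140 (0.77, 0.497), did not pass, nor did Ghrl (-2.09, 0.645) and Gast (-1.45, 0.833). Of 12 hormones 2 differed, 4 in one direction and 2 in the other adjusted over the list alone (camera adjusted p = 1.59e-05; adjusted p = 0.0419 with an estimated correlation; list median 0.783). Without the pairs with markers of another organ Gip (3.4, adjusted p = 0.07) and Nts (3.37, adjusted p = 1) did not pass, and 1 other gene did.

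Between older (P10 to P20) and younger (P1, P5) small intestine, the genotype effect differed for 0 of 12733 genes in limma, with 743 at an unadjusted p under 0.05. The smallest p belonged to Trim30d (log2 difference 2.94), Taf1d (-1.70) and Trim12a (1.79), at adjusted p = 0.206. Slc34a2 and Gnb5 came next and did not pass either. The hormone list passed (camera adjusted p = 0.0442; adjusted p = 0.63 with an estimated correlation), and so did exocrine pancreas (6.20e-08; adjusted p = 0.63 with an estimated correlation). Without bottom intestine at P10, 3 genes passed.

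Age was compared in small intestine in a fit that held both genotypes. The 2 libraries of each of the 7 pairs counted as separate in it, so that p-values may be too small. Other groupings of whole stages gave up to 487 calls, against 753. The Paneth cell genes Defa22 (2.96 log2, adjusted p = 0.00245) and Ang4 (2.41) rose, as did Pla2g2a (3.11, 0.00032), Gm14850 (3.25, 0.000465) and Apol10a (2.99, 0.000544), in 6 older against 8 younger libraries. Sucrase (Sis, 2.76, adjusted p = 0.00891), Arg2 (2.30) and trehalase (Treh, 1.99) of the weaned intestine rose, and the fetal liver gene Afp (-1.93, 0.0354), Igf2as (-2.64, 0.000545), Abcb11 (-1.87, 0.0154), E030010A14Rik (-2.03, 0.0482), Bex4 (-1.86, 0.00658) and the hormone Insl5 (-1.19, 0.0394) fell. Edf1 also passed (3.42), but was listed at 0 in 10 of 14 libraries. Of 13 crypt stem genes 10 rose, 13 adjusted over the list alone (Lgr5 1.06, Axin2 1.06; camera adjusted p = 1.48e-11; adjusted p = 0.0916 with an estimated correlation). Of 19 granule genes 8 rose, with 11 rises and 1 fall adjusted over the list alone (8.42e-08; 0.0916), of 15 smooth muscle genes 7, or 12 (1.68e-08; 0.207), of 6 Paneth genes 3, or 5 (0.000183; 0.207), and of 10 weaned enterocyte genes 4, or 4 (0.00443; 0.492), the last value of each being the adjusted p with an estimated correlation. Of 9 liver genes 4 fell, 7 adjusted over the list alone (3.53e-05; adjusted p = 0.0916 with an estimated correlation). In all 753 of 12733 genes passed, 452 higher and 301 lower. The count was 131, 274, 84, 291 and 425 without bottom intestine at P1 or P20 or top intestine at P15, P1 or P5, and 46 without the pairs with markers of another organ. Treh, Afp, E030010A14Rik and Insl5 lost their calls in at least 5 of the 7 omissions of 1 pair, Abcb11 and Arg2 in 3, Sis in 2, and Bex4 and Axin2 in 1, top intestine at P15.

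Stomach differed from small intestine in 6322 of the tested genes, 3409 higher and 2913 lower in stomach. The 24 libraries of 12 pairs counted as separate in this fit too, so that p-values may be too small. The proton pump gene Atp4a had 58.1 ± 21.4 FPKM in 10 stomach and 3.66 ± 7.67 in 14 intestine libraries (SD, log2 4.12), and the squamous genes Krt1, Sprr3, Krt4 and Rptn were higher by 4.16, 4.15, 4.10 and 4.10. The starch-digesting Mgam had 2.24 ± 3.32 against 62.9 ± 18.9 FPKM (-4.76), and Slc7a9, Clec2e and Ush1c were lower by -4.67, -4.66 and -4.35. G630016D24Rik was listed at 0 in the 10 stomach libraries. Among hormones Gast (2.47, adjusted p = 2.19e-05), Sst (1.43) and Ghrl (0.96, 0.0246) were higher in stomach and Sct (-2.62), Nts (-1.73), Gip (-1.72) and Cck (-1.36) lower, in a fit that pooled both genotypes. Wild type alone is given in rescaled FPKM, so its means differ slightly from those as deposited. Stomach and intestine had 47.2 ± 8.3 against 11.2 ± 4.73 of Ghrl (SD, n = 5 and 7), 1.14 ± 0.831 against 22.6 ± 6.21 of Gip and 0.224 ± 0.183 against 14.2 ± 6.87 of Nts. Of 18 parietal and chief cell genes 16 were higher (camera adjusted p = 5.14e-09; adjusted p = 0.134 with an estimated correlation), as were 16 of 16 gastric mucous (3.06e-08; adjusted p = 0.224 with an estimated correlation) and 10 of 10 forestomach genes (3.25e-07; adjusted p = 0.208 with an estimated correlation). Of 28 enterocyte genes 26 were lower (2.93e-20; adjusted p = 0.103 with an estimated correlation). The call of Ghrl ended without bottom intestine at P10 or stomach at P5 or, in its bottom part, P10.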

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

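The tests of chromosome 17, of the endocrine genes, of the organ markers and of other splits of the samples were chosen after the results were seen, while the difference between regions was a fixed comparison.

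Called genes crowded on chromosome 17, with 29 of the 116 called over all pairs. The targeted allele came from 129S6 cells, and the genes beyond 500 kb of the stated positions also passed more often than genes elsewhere (odds ratio 6.31, Fisher's exact p = 2.03e-11). An effect of the deletion on its neighbours alone is argued against, since 86.2 percent of the 29 lie farther than 500 kb. Loss of reads of 129S6 sequence in mapping to the C57BL/6 reference stays open for the 15 genes that were lower. It is argued against for the 14 that were higher only if wild type held C57 sequence at these genes. On this mixed background that was not examined. Linked 129S6 sequence may therefore account for these calls, and Fkbp5, C3, Hagh and Tagap1 lie on this chromosome.

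Peptide hormones fell while Tph1, Chga and Chgb rose; the enteric neuron list was positive in 19 of 19 genes (adjusted p = 0.28 with an estimated correlation), and since these neurons also express Chga and Chgb, a neuronal source of their rise stays open. Fewer enteroendocrine cells of every type would not by itself account for the rise of Tph1. That rise is part of the pattern, however, and may lie within cells, so it cannot decide. The granule and amine genes had a median log2 change of 0.0302, which cannot decide, since the list holds genes that neurons express too. Tissue of another organ in a library is argued against, since the hormone mean was -1.87 in the 9 pairs without gastric, pancreas, liver or enterocyte markers, with the list filtered anew, and with its members kept -1.78 there (exact p = 0.00391) and -1.99 also without the whole gut and bottom stomach at P15 (exact p = 0.0156, the smallest 7 pairs can give); the largest islet differences (-2.24, -1.91 and 2.34) lay in pairs left out. As a hypothesis, peptide hormone cells may be lost and enterochromaffin cells kept. Slc18a1 and Ddc, the other tested enterochromaffin genes, changed by a mean of -0.00225 (95 percent interval -0.128 to 0.124, SD 0.237, 16 pairs, permutation p = 0.971). Slc18a1 was lower in 5 and higher in 2 of 7 small intestine pairs (9.93 against 12.1 FPKM in wild type), and lower in 2 and higher in 3 of 5 stomach pairs. Ddc had 8.22 FPKM in wild-type whole gut, where Tph1 was listed at 0, so it may not follow these cells. Their mean thus bears weakly on the hypothesis. Bulk RNA cannot separate a change of cell number from a change within cells, and neither was measured.

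Gastric, pancreas, liver or enterocyte markers of another organ differed by over 1 log2 unit in 7 of 16 pairs. They were gastric mucous genes in colon at P5 (1.64), bottom intestine at P5 (1.12) and top intestine at P1 (1.16) and P5 (-1.61), forestomach genes in bottom intestine at P5 (3.12), parietal genes in top intestine at P1 (1.51), pancreas genes in top intestine at P1 (-2.33) and P5 (-2.68), bottom stomach at P10 (1.67) and stomach at P1 (-2.23) and P5 (-1.71), enterocyte genes in stomach at P1 (1.12) and liver genes in stomach at P5 (3.51). Members of such a list mostly differed in one direction (median 93.8 percent). The lists were picked for a mean past 1 log2 unit, which favours such a share, so it cannot decide on neighbouring tissue. A change of gastric genes with genotype is argued against, since the gastric mucous list had a median ratio of 0.113 over the 10 postnatal bowel pairs, with pairs past 1 in both directions. Neighbouring tissue may be the source, which stays a hypothesis, since dissection was not recorded per library.

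Of 59 groups of 4 to 10 values searched for one far from the rest, 7 had one, and chance gives about 1 in 20 groups (2.95 here). Besides the forestomach and liver values above, the gastric mucous ratio of stomach at P1 was -1.4 (others -0.109 to 0.255). In top intestine at P15 the log2 ratio of Nts was -1.515 (others -4.162 to -3.189) and of Sct 0.7489 (others -1.297 to -0.5077). In bottom intestine at P5 that of Tac1 was 1.245 (others 0.2496 to 0.6795). The wild-type library of bottom intestine at P10 held 214400 records (others 122200 to 156000).

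The genotype effect differed between stomach and small intestine for Gip (3.6), Nts (3.3) and the hormone list (median 0.783). The falls possible in stomach were 1.02 for Gip and 0.28 for Nts, so a smaller fall there followed from the low wild-type level. Cck, Sct and Insl5 were low in wild-type stomach too (1.14, 0.65 and 0.0856 rescaled FPKM against 10.9, 13.7 and 2.54 in intestine). Gast was low in wild-type intestine instead (0.68 against 17.1 in stomach). The list difference thus cannot be parted from these levels. In records without a symbol, which no comparison used, records lay wholly inside the stated deleted positions in 4 percc1-/- libraries and in 0 of 16 wild-type ones, while a wild-type record of bottom intestine at P10 (25174439 to 25175185, 1.28 FPKM) reached into them. The values were 3.493 FPKM in colon at P5, 1.345 in bottom intestine at P1, 1.838 in bottom stomach at P20 and 1.918 in stomach at P5.

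With the 16 pairs taken as independent, swaps of genotype within pairs excluded chance for all pairs (1 of 100 splits as large, the real one; 116 against a highest other of 1) and small intestine (1 of 64; 15 against 1). The parts of the small intestine share P1 and P5, however, and its stages were not swapped whole, so chance stays open for its count. Regions share stages too, and over all pairs, with the pairs of a stage swapped together, 3 of 32 splits were as large, which does not exclude chance for the count. The others swapped the whole gut alone (171) or with P20 (137), and so left all but 1 or all but 3 of the pairs as they were. The hormone list averaged within stages was -1.64, lower in 6 of 6 stages (exact p = 0.0312, the smallest 6 can give). Whole pairs regrouped within stages gave fewer calls for the difference between regions (1 of 72 as large, 2 against 0). Its calls were Gip and Nts, low in wild-type stomach, and regrouping mixed these levels too. These splits therefore cannot part a difference of effect from the levels. For stomach against small intestine such splits excluded chance (1 of 72, 6322 against 4374). Regrouped across stages, these comparisons gave 1 and 4391 at most (1 of 100 each). For stage in small intestine the 5 stages allow 10 splits, too few (753 against 487), while pairs taken as independent gave 330 at most (1 of 34). Single libraries regrouped, which parts the pairs, gave 29 at most for stage (1 of 100) and 2278 for stomach against small intestine (1 of 100). For the difference between stages, with 0 calls, the splits test nothing (35 of 35 as large; highest other 2). The splits are too few for stomach (16; 3 against 1) and large bowel (4; 6 against 0).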

How the results depend on the processing

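Leaving out pairs with markers of another organ, or these with the whole gut and bottom stomach at P15, leaving out chromosome 17 and keeping merged records were chosen after the data were seen; the other settings were fixed before. The cause of a change was not tested except where fewer genes or pairs entered. Over all pairs (116 genes) the count was 59 at a mean of at least 5 FPKM, 44 with no replicate block, 2 with stage-averaged differences, 62 with stage and genotype as a random block, 9 without the organ-marker pairs, 3 also without the whole gut and bottom stomach at P15, 59 without chromosome 17, and 68 to 182 on leaving out 1 pair. In small intestine (15) it was 4 with a pseudocount of 0.1, 3 with no filter, 26 with quantile normalization, 23 with array weights, 1 stage-averaged, 2 in the top part only, 4 in the bottom part only, 1 without the organ-marker pairs and 2 to 19 without 1 pair. In stomach (3) it was 1 with a pseudocount of 0.1, 1 at 5 FPKM, 7 unscaled, 5 with no replicate block, 0 in the bottom part only, 0 without the organ-marker pairs and 1 to 3 without 1 pair. In large bowel (6) it was 0 with a pseudocount of 0.1, 0 with no filter, 1 at 5 FPKM, 3 with quantile normalization, 2 with array weights, 0 without the organ-marker pair, 2 with merged records kept and 0 to 28 without 1 pair, where limma pools the spread. By region (2) it was 4 with no filter, 1 at 5 FPKM, 1 without the organ-marker pairs and 2 to 3 without 1 pair; by stage (0) it was 1 with a pseudocount of 0.1 and 0 to 3 without 1 pair. For stage (753) it was 347 at 5 FPKM, 46 without the organ-marker pairs and 84 to 857 without 1 pair; for stomach against small intestine (6322) 4082, 3618 and 5411 to 6136. Unscaled values moved the median of all genes by 0.101 there and by 0.137 in the difference between stages. The number of called lists (8) was 7 to 10 without 1 pair, with goblet losing its call in 6 omissions and pancreas in 1. The hormone mean kept its sign in every setting run, from -1.96 to -1.79 over all pairs, -2.26 to -2.0 in small intestine, -2.05 to -1.47 in stomach and -2.03 to -1.86 in large bowel without 1 pair; in small intestine it was -2.32 without the organ-marker pairs (exact p = 0.125) and -2.04 stage-averaged (exact p = 0.0625), with too few values to pass. Its members were filtered anew in each setting: also without the whole gut and bottom stomach at P15 it was -2.14 over all pairs, against -1.99 with the members kept. There the pancreas (0.109, camera adjusted p = 0.274) and smooth muscle lists (-0.0912, 0.00926, so that smooth muscle passed) turned. Signs turned without the organ-marker pairs for the pancreas (0.056, camera adjusted p = 0.611) and liver lists (-0.182, 0.0153, so that liver passed). Signs also turned there for Tac1 by region (0.135), for stage in Sct (0.0472), Pyy (0.0752), Gcg (0.182), Cck (0.363) and Ghrl (-0.0396), and between stomach and intestine in Chgb (0.0305). With a pseudocount of 0.1 they turned for Iapp in stomach (-0.225), for stage in Cck (0.208) and Gip (-0.336), and for Gcg between stomach and intestine (0.0455). Pyy by stage turned with array weights (0.27). Without 1 pair, ranges that crossed 0 were -1.52 to 0.63 for Pyy and -0.107 to 1.16 for Nts by stage, -0.0859 to 0.218 for Tac1 and -0.371 to 0.0448 for Cck with stage, and -0.0311 to 0.314 for Pyy between stomach and intestine. Of 5531 checks of 280 results for single genes, 4772 kept direction and side of the threshold, 722 lost the call, 16 gained it and 21 reversed. Depth limits genes near 1 FPKM, where a fall cannot exceed the wild-type level.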

Other observations

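The values in this part were examined after the results were seen, except for the list membership, which was fixed before.

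Members of the fixed antimicrobial and interferon list differed in sign, while the list as a whole did not pass (camera adjusted p = 0.232). Its 7 tested interferon-induced members had a mean log2 change of -0.28 ± 0.227 (SD, n = 16 pairs), with 0 called higher and 1 lower. The 10 other members had a mean of 0.89 ± 0.765, with 4 called higher. This division was made after the values were seen, so a test of it would not be independent evidence, and none is given. The leukocyte list also fell over all pairs (camera adjusted p = 0.00514; adjusted p = 0.63 with an estimated correlation) and in small intestine (15 of 15 negative), and its median was -0.16 without the organ-marker pairs. Of 12 further interferon genes chosen because they had passed, such as Irf1, Oasl2, Mx2 and Xaf1, 12 fell, with a mean of -0.54 ± 0.26, and 6 of 10 tested neutrophil genes rose, so that neither count is independent evidence.

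Of 37 tested genes within 500 kb of the stated positions, 4 passed over all pairs. They were Igfals (-0.95, adjusted p = 0.0015), Snhg9 (-0.52, 0.0128), Fahd1 (-0.46, 0.00151) and Hagh (-0.38, 0.0162), all lower in percc1-/-.

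Unnamed records lay over Ghrl in 31 of 32 libraries (1.69 to 11.7 FPKM). Whether they hold Ghrl transcripts was not tested. With these added, the summed value was lower in percc1-/- in 5 of 5 stomach pairs (5.54 to 10.6 against 39.9 to 67.9 FPKM) and in 7 of 7 small intestine pairs (3.24 to 13.6 against 14.4 to 23.7). It was higher in percc1-/- in colon at P5 (7.30 against 6.63), rectum at P5 (10.1 against 5.03) and the whole gut (9.55 against 9.44), and lower in colon with rectum at P1 (6.30 against 9.49).

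Sex-linked genes gave the same signal in both libraries of 16 of 16 pairs. Xist exceeded the Y-linked genes in the 4 libraries at P10 and lay below them in the other 28, so this agreement is a weak check. In the age comparison 2 of the 6 older intestine libraries thus differed in sex from the rest, and without bottom intestine at P10 857 genes passed, against 753.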
